A study of Homo sapiens with 6 samples.

How the data were processed

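Total RNA of human CD34 cells transduced with AML1-ETO, the fusion protein of the t(8;21) leukaemia translocation, or with the empty vector MIGR1 was measured on Affymetrix U95 arrays, and the cells were not selected after transduction, per the labels. The 6 arrays form 2 groups of 3, taken with their replicate numbers from the sample titles. The titles also carry the codes CB (replicates 1 and 2) and PB (replicate 3), which the labels do not spell out and which are used here only as codes. The labels do not say whether replicates came from separate cultures or donors, so p-values measure only the spread between these samples, which may be partly technical.

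The deposited values are signal intensities on a linear scale, 1 per probe set and array, with no value below 0. On every deposited array the mean trimmed by 2% at each end was about 500, and these means differed by at most 0.02% between arrays, so each array had already been scaled to a common mean. The tool that made the intensity values and its version are not given in the sources used here. The arrays come in 2 tables of different array designs: 1 holds 12625 probe sets on 4 arrays (replicates 1 and 3 of both groups) and the other holds 12626 probe sets on 2 arrays (replicate 2 of both groups).

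The 12600 probe sets shared by both tables were used, and 67 control probe sets among them were left out, which left 12533. Of these, 10919 had 1 gene symbol in the platform annotation of 2016, 545 had several and 1069 had no symbol listed. Gene numbers matched the RefSeq gene table for 10910 of the probe sets with 1 symbol. No gene was named from a probe set with several symbols. The remaining 25 and 26 probe sets in only 1 table entered no test.

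Each array was scaled to a trimmed mean of 500 over the shared probe sets, values under 50 were raised to 50, and log2 was taken. The rule set beforehand added quantile normalization only if trimmed means differed by over 5%, so it was run as an alternative. Probe sets at 100 or more on at least 2 arrays were tested, which gave 9791 probe sets of 6829 genes. Values at the floor of 50 have no order. A fold against a group whose arrays are all at the floor is a lower bound, written as at least that fold.

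Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with the table as a fixed term, so that levels were compared only within a table, and p-values were adjusted by Benjamini-Hochberg at 0.05. Mean log2 ratios are given ± SD over the 3 pairs (AML1-ETO over empty vector of the same replicate number). A second description, with no p-value, counted probe sets 2-fold or more higher, or lower, in every pair.

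Whether the replicate numbers pair the arrays was checked from the data. Deviations from the group means correlated within pairs 1, 2 and 3 with r = 0.682, 0.241 and 0.456 across probe sets, which are not independent replicates. All 6 arrays correlated best with the array of their own number, and the highest correlation between arrays of different numbers and groups was 0.129. Pair 2 is alone on its array design, so its correlation is not separate from the design. Pairs 1 and 3 share a design but differ by code, so their correlations are not separate from the code. By the rule used, over 0.1 in every pair, the numbers were taken to pair the samples. This pairing comes from the data and not from a statement in the labels. The check cannot tell a shared culture or donor from a shared code, array design or processing of the arrays. The fit with the replicate number as a block was an alternative.

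Before the data were examined, 23 gene lists of at least 3 genes were fixed: fusion partners, reported higher with AML1-ETO, reported lower with AML1-ETO, stem and progenitor, erythroid, neutrophil granule, monocyte and macrophage, megakaryocyte and platelet, mast cell with basophil and eosinophil, T and NK lymphocyte, B lymphocyte, MHC class II and dendritic cell, DNA replication, mitosis, p53 targets, DNA repair, cytokine receptors, interferon response, NF-kB and inflammatory cytokines, Notch and Wnt, immediate early and heat shock, cholesterol and sterol synthesis, and ribosomal protein. Lists with at least 5 tested genes, 22 in all, were tested by limma's camera with a preset correlation of 0.01, with 1 probe set per gene (the highest mean). The fusion partner list was too small for this test. Percentiles of list medians come from 10000 random lists of the same size matched on mean expression.

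The genes named were fixed by a rule set before the data were examined: RUNX1T1, RUNX1 and a gene that is not reported here, and the 12 genes with the largest positive and the 12 with the largest negative mean log2 ratio past the adjusted threshold and in the same direction in every pair. Where too few passed, places were filled by the largest mean log2 ratio among probe sets 2-fold or more different in the same direction in every pair, with 1 probe set per gene, the one with the larger difference. For each list described, up to 4 members with the largest difference in the same direction in every pair were added.

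The alternatives were the replicate block, quantile normalization, floors of 20 and 100, log2(value + 50), no filter, a filter at 200, the 4 arrays of the larger table alone, an intensity trend, an ordinary t statistic, 1.5-fold in place of 2-fold, an estimated correlation and fry for the lists, and leaving out each replicate. Array weights, the GAPDH 3'/5' ratio as a covariate, the estimated correlation together with the block, and quantile normalization and other floors for the PB and CB comparison were added after the data were seen. The GAPDH 3'/5' ratio also differed between pair 1 and the other pairs, so a fit with it cannot separate RNA quality from the replicate.

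The fit was tested on simulated data for the comparison of AML1-ETO with empty vector: 20 simulations of 9791 probe sets, with 200 altered in each. It called 1.11% of the probe sets altered 2-fold, 18.3% of those altered 4-fold, 65.3% of those altered 8-fold and 91.6% of those altered 16-fold, with a mean of 4.35 false calls among 93.3. With the erythroid list lowered by 0.5 on the log2 scale and genes otherwise independent, camera called it in 75% of 20 simulations. The simulated noise was independent between arrays and of the same spread on each. The real arrays correlate within pairs, so these rates may not hold for them. The number of arrays limits the precision.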

Results

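Gene expression was compared between human CD34 cells transduced with AML1-ETO and cells transduced with the empty vector MIGR1. The comparison was made to find genes whose level differs with the fusion protein. The cells were not selected after transduction, so untransduced cells may be among them, in a share not given in the sources used here. This share may differ between arrays, and the folds and counts below are those of the mixed cells. CD34 marks blood stem and progenitor cells. Each group had 3 arrays, which form 3 pairs by replicate number: pairs 1 and 2 have the code CB and pair 3 has the code PB. The median deposited intensity ranged from 148.4 to 238.5 over the 6 arrays, and between 4.739% and 15.58% of the tested values of an array were at the floor.

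Several control probe sets differed more between the groups in pairs 2 and 3 than in pair 1. The GAPDH 3'/5' ratio, a measure of RNA integrity, was 1.07 in AML1-ETO and 1.08 in empty vector in pair 1. It was 1.47 against 2.04 in pair 2 and 1.43 against 1.94 in pair 3. The actin 3'/5' ratio was 1.17 against 1.15 in pair 1 and 1.39 against 1.79 in pair 2 but 1.23 against 1.28 in pair 3, so that the 2 controls differ on pair 3. The 18S rRNA signal was 462.9 against 334.4, 1097 against 2206 and 3790 against 11030 in pairs 1, 2 and 3. The signal of the spike-in controls was 1.04-fold higher in the vector array of pair 1, 1.19-fold higher in pair 2 and 2.25-fold higher in pair 3. In AML1-ETO and empty vector its geometric means were 4636 and 4801 in pair 1. They were 29690 and 35390 in pair 2 and 26230 and 59120 in pair 3. Pair 1 thus also differed in level from the other pairs, and the reason is not given in the sources used here. The SD of the log2 ratios between the arrays of a pair was 0.57, 0.89 and 1.12 in pairs 1, 2 and 3. Across probe sets, which are not independent replicates, the log2 ratios of different pairs correlated with r = 0.0769 (pairs 1 and 2), 0.128 (pairs 1 and 3) and 0.0625 (pairs 2 and 3).

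**Figure D1:**
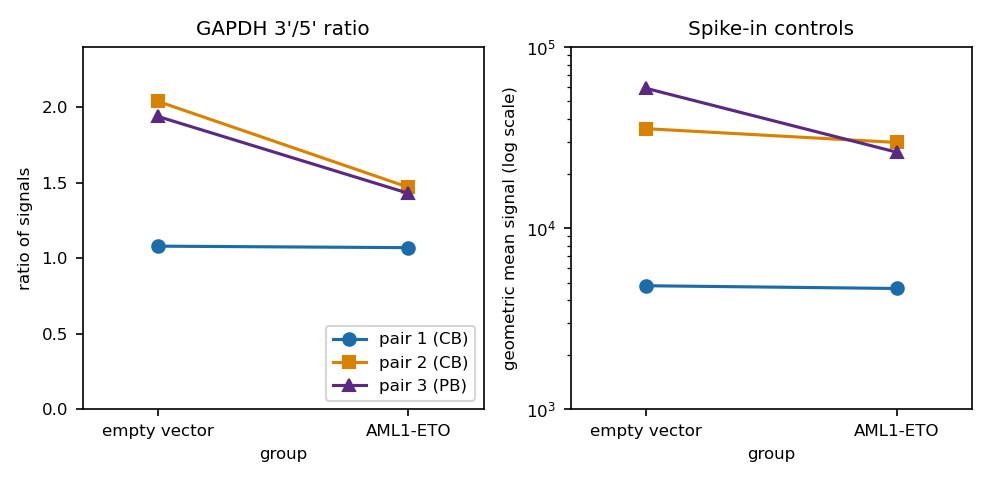
GAPDH 3'/5' signal ratio (left) and geometric mean signal of the spike-in controls on a log axis (right) by group; each line joins the 2 arrays of a pair. The 3'/5' ratio was 2.04 and 1.94 on the vector arrays of pairs 2 and 3, against 1.47 and 1.43 on their AML1-ETO arrays, and 1.08 against 1.07 in pair 1.

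RUNX1T1, which encodes the ETO part of the fusion, was measured first as a check of the labels. Its only tested probe set was at least 3.36-fold higher in AML1-ETO, with a mean log2 ratio of 1.75 ± 0.87 (SD, n = 3 pairs) and ratios of 1.22, 1.28 and 2.76; all 3 vector arrays were at the floor. Scaled values were 116.1, 121.2 and 338.1 in AML1-ETO and 2.018, 15.26 and 49.76 in empty vector. It did not pass the test (limma, adjusted p = 1). Of the 3 other RUNX1T1 probe sets, none passed the expression filter. Of these, 1 was higher in AML1-ETO in each pair (74.71 against 60.93, 188.6 against 40.4 and 53.02 against 25.6), whereas another was lower in pair 3 (18.42 against 105.6) and the remaining 1 was lower in pair 2 (18.46 against 72.86). Whether any of them lies in the cloned sequence is not given in the sources used here. RUNX1, the AML1 part, had no probe set with a single symbol (6 listed several), so it was not analysed here.

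No probe set passed the test for a difference between AML1-ETO and empty vector (limma, 0 higher and 0 lower, smallest adjusted p = 0.327). At an unadjusted p under 0.05 there were 107 higher and 74 lower, 181 in all, where 490 of the 9791 tested would be met by chance. With the replicate block the count was also 0 (smallest adjusted p = 0.629), with 608 at an unadjusted p under 0.05. The fit without the block has no term for the replicate. Differences between pairs 1 and 3 then enter its spread and can raise its p-values. The shortfall of 181 from 490 is thus no measure of how many probe sets differ. An ordinary t statistic gave 0. Modelling the spread by intensity gave 5 calls, namely 3 CYP1A1 probe sets, S100A8 and S100A9 (adjusted p from 0.0227 to 0.0479), and array weights, added after the data were seen, gave 4, namely 2 CYP1A1 probe sets, APOE and a probe set with no gene named here (adjusted p from 0.00362 to 0.0469).

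By size alone, 34 probe sets were 2-fold or more higher in AML1-ETO in every pair (25 genes with 1 symbol) and 24 were 2-fold or more lower (22 genes). With the direction of 1 pair turned, the totals were 21, 26 and 22, against 58. Over all tested probe sets 2512 (25.7%) had the same direction in every pair, where 25% would be met by chance; among the 8523 with a difference in each pair the share was 29.5%. The genes below are given as values, since none passed the test.

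CYP1A1, a cytochrome P450 that oxidises foreign aromatic compounds, showed the largest difference: 31.8-fold higher in AML1-ETO, with a mean log2 ratio of 4.99 ± 1.05 (SD, n = 3 pairs; limma, adjusted p = 0.327). Because 2 of 3 vector arrays were at the floor, its size depends on the floor: 48.7-fold at a floor of 20 and 17.4-fold at a floor of 100. The mean was 4.38 without replicate 1. Its other 2 probe sets had means of 4.61 and 4.49. APOE, a lipoprotein component made by macrophages among other cells, was 10.3-fold higher (3.37 ± 0.65, adjusted p = 0.615). NPTX1, a neuronal pentraxin, was at least 8.54-fold higher (3.10 ± 0.65), with all vector arrays at the floor. ID1, an inhibitor of helix-loop-helix transcription factors, was 4.2-fold higher (2.07 ± 0.38), and its other probe sets had means of 1.23 and 0.99. CKB, a creatine kinase, was 4.17-fold higher (2.06 ± 0.52) and PLIN2, a lipid droplet coat protein, 3.51-fold higher (1.81 ± 0.55). TM4SF1, a membrane protein, was at least 3.49-fold higher (1.80 ± 0.56). CH25H, a cholesterol hydroxylase, was 3.38-fold higher and PROCR, the endothelial protein C receptor, 3.34-fold higher. BFSP2 (2.11 ± 0.80) and SNX29 (1.73 ± 0.59) completed the genes with higher values, but another probe set of each went the other way (-0.36 for BFSP2 and -0.43 for SNX29).

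Among genes with lower values in AML1-ETO, several belong to myeloid cells. FCN1, a ficolin of monocytes, had a mean log2 ratio of -3.10 ± 0.91 (SD, n = 3 pairs, 0.117 of the vector value). S100A8 and S100A9, calcium-binding proteins abundant in monocytes and neutrophils, had means of -2.56 ± 0.70 and -2.18 ± 0.31. CTSG, the granule protease cathepsin G, had -1.77 ± 0.15, and its other probe set -1.47; MS4A3, of granulocyte precursors, had -1.78 ± 0.28. CD1C and CD1B, which present lipid antigens on dendritic cells, had -1.80 ± 0.89 and -1.76 (pair ratios -1.33, -1.05 and -2.91). BLNK, a linker of B cell receptor signalling, had -2.17 ± 0.24, with all 3 AML1-ETO arrays at the floor, which makes it a bound. AP1S2 had -2.26 ± 1.34 (-2.88 without replicate 1 and -1.55 without replicate 3), LMOD1 -1.77 ± 0.62 and GPER1 -1.74 ± 0.85. OGG1, which excises oxidised guanine, had -2.28 ± 1.09 by 1 probe set, while its 4 others had -0.43, -0.69, -1.05 and 0.57. In these pairs the vector arrays of pairs 2 and 3 also had the higher GAPDH 3'/5' ratios given above.

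**Figure D2:**
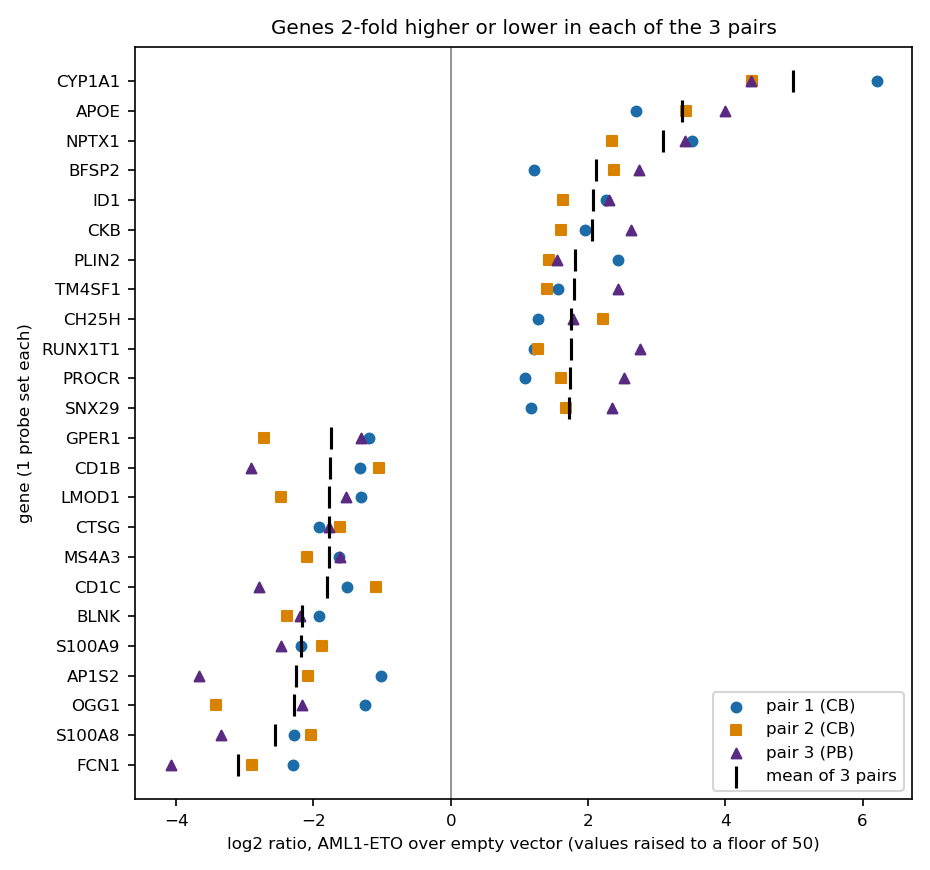
Log2 ratio of AML1-ETO over empty vector (x axis) for the 24 genes named by size (y axis); symbols show the 3 pairs and bars their mean. Every gene lies at least 2-fold from 0 on the same side in each pair, from CYP1A1 (mean 4.99) to FCN1 (mean -3.10); none passed the test.

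Of the 22 gene lists tested, 7 passed camera with a preset correlation, 1 higher and 6 lower in AML1-ETO. None held with an estimated correlation (smallest adjusted p = 0.65 with an estimated correlation). None held by fry either (smallest adjusted p = 0.71), which tests a list without comparing it with other genes. Neither failure counts firmly against a list. With an estimated correlation, camera judges each list on the few residual degrees of freedom of 6 arrays, which made passing hard at any correlation. For the MHC class II and dendritic cell list the estimate was 0.023, near the preset 0.01. Yet camera's adjusted p for it went from 0.015 to 0.65. Fry was run only without the replicate block, so differences between pairs entered its spread. No member of any list passed the test over all probe sets.

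The monocyte and macrophage list fell (28 genes tested, median log2 ratio -0.54, camera adjusted p = 7.5e-05; adjusted p = 0.65 with an estimated correlation). In every pair 10 of its genes were lower and 1, APOE, was higher. Adjusted over the list alone, 4 genes passed: S100A8, S100A9, FCN1 and APOE. Its medians were 0.00, -0.28 and -1.28 in pairs 1, 2 and 3 while the GAPDH 3'/5' ratio was higher on the vector arrays of pairs 2 and 3 and the actin ratio mainly on that of pair 2. Without replicate 3 the median was -0.12.

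The erythroid list fell (21 genes, median -0.47, adjusted p = 2e-04; adjusted p = 0.65 with an estimated correlation), with 13 genes lower and 0 higher in every pair. NFE2, a transcription factor of erythroid cells and megakaryocytes, had -1.58 ± 0.66 (SD, n = 3 pairs), and the globins HBD, HBB and HBE1 had -1.53 ± 0.73, -1.26 ± 0.83 and -1.10 ± 0.29. Globin genes are near-identical in part, so signal could be shared between them. The list medians were -0.62, -0.30 and -0.79 in pairs 1, 2 and 3, where the vector GAPDH 3'/5' ratio was higher in pairs 2 and 3 and not in pair 1. With the GAPDH 3'/5' ratio as a covariate the median was -0.26.

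The neutrophil granule list fell (20 genes, median -0.56, adjusted p = 0.019; adjusted p = 0.75 with an estimated correlation), with 9 genes lower and 4 higher in every pair. CTSG and CYBB, a subunit of the oxidase of phagocytes, had -1.77 ± 0.15 and -1.30 ± 0.47, whereas LTF and TCN1, proteins of secondary granules, had 1.13 ± 1.46 and 0.91 ± 0.20. Pair medians were -0.05, -0.54 and -0.83. The call was lost without replicate 2 (median -0.46, adjusted p = 0.11), the median was -0.37 without replicate 3, and with the 3'/5' ratio as a covariate the median was 0.13 (adjusted p = 0.82). The MHC class II and dendritic cell list fell (26 genes, median -0.27, adjusted p = 0.015; adjusted p = 0.65 with an estimated correlation), with 13 genes lower and 2 higher in every pair. CD1C, CD1B and CD1E (-1.48 ± 1.33) were lower, and IL3RA, an interleukin receptor chain, was higher (1.42 ± 0.68). Pair medians were -0.08, -0.34 and -0.57; the call was lost without replicate 1 (adjusted p = 0.059) and with the covariate (adjusted p = 0.096), although the medians of -0.39 and -0.29 were no smaller in size.

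The DNA replication list fell (35 genes, median -0.29, adjusted p = 0.02; adjusted p = 0.75 with an estimated correlation), with 12 genes lower and 2 higher in every pair. Examples were MCM3 (-0.77 ± 0.23), a subunit of the replicative helicase, RFC3 (-0.70 ± 0.29), CDC6 (-0.67 ± 0.25) and FEN1 (-0.67 ± 0.38). Its medians were -0.57, -0.04 and -0.28 in pairs 1, 2 and 3, the largest being in the pair with like 3'/5' ratios by both controls, and the call was lost without replicate 1 (median -0.14, adjusted p = 0.82). With the 3'/5' ratio as a covariate the median was -0.60.

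The list of genes reported higher with AML1-ETO rose (13 genes, median 0.53, adjusted p = 0.0017; adjusted p = 0.65 with an estimated correlation), with 4 genes higher and 0 lower in every pair: ID1, JUP (1.55 ± 0.29), CDKN1A (0.86 ± 0.40) and POU4F1 (0.53 ± 0.40). ID1 passed adjusted over the list alone. Pair medians were 0.18, 0.90 and 0.00. The median was 0.30 with no filter on low values and 0.92 with the 3'/5' covariate. The list reported lower with AML1-ETO fell (15 genes, median -0.57, adjusted p = 0.02; adjusted p = 0.75 with an estimated correlation), with 7 genes lower and 3 higher in every pair, among them CTSG, RASSF2 (-1.10 ± 0.14) and IGFBP7 (-1.03 ± 0.47) on the lower side and LTF on the higher. Pair medians were -0.25, -0.73 and -0.54; the call was lost without replicate 2 (median -0.35, adjusted p = 0.21) and with the 3'/5' covariate (median -0.17, adjusted p = 0.76). Both lists come from general knowledge of AML1-ETO, and some of their genes could first have been found in these samples, so their direction is not independent evidence.

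The other 15 lists did not pass with the settings used throughout (adjusted p from 0.10 to 0.98). Their medians were -0.38 for mast cell, basophil and eosinophil, -0.20 for DNA repair, -0.16 for mitosis, -0.14 for megakaryocyte and platelet, -0.14 for NF-kB and inflammatory cytokines, -0.10 for B lymphocyte, -0.09 for T and NK lymphocyte and -0.04 for cholesterol and sterol synthesis. They were 0.11 for p53 targets, 0.08 for immediate early and heat shock, 0.04 for ribosomal protein, 0.03 for interferon response and 0.02 for stem and progenitor. For cytokine receptors (median -0.03, mean 0.01) and Notch and Wnt (median -0.10, mean -0.06) camera's direction was up, against the median. With the replicate block the mast cell, basophil and eosinophil list passed as well (adjusted p = 0.019, against 0.10), but not with the block and an estimated correlation (adjusted p = 0.53 with an estimated correlation). It also passed with log2(value + 50) (adjusted p = 0.046), the filter at 200 (median -0.69, adjusted p = 0.041), without replicate 1 (median -0.85, adjusted p = 0.025) and without replicate 3 (median -0.24, adjusted p = 0.019), whereas its median was -0.10 with the GAPDH 3'/5' covariate (adjusted p = 1). The mitosis list passed with the GAPDH 3'/5' covariate (median -0.46, adjusted p = 8.1e-05), and the NF-kB and inflammatory cytokine list without replicate 3 (median -0.29, adjusted p = 0.019). Over all arrays and without the covariate these had adjusted p = 0.82 and adjusted p = 0.75 with an estimated correlation, which was not run in those settings.

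**Figure D3:**
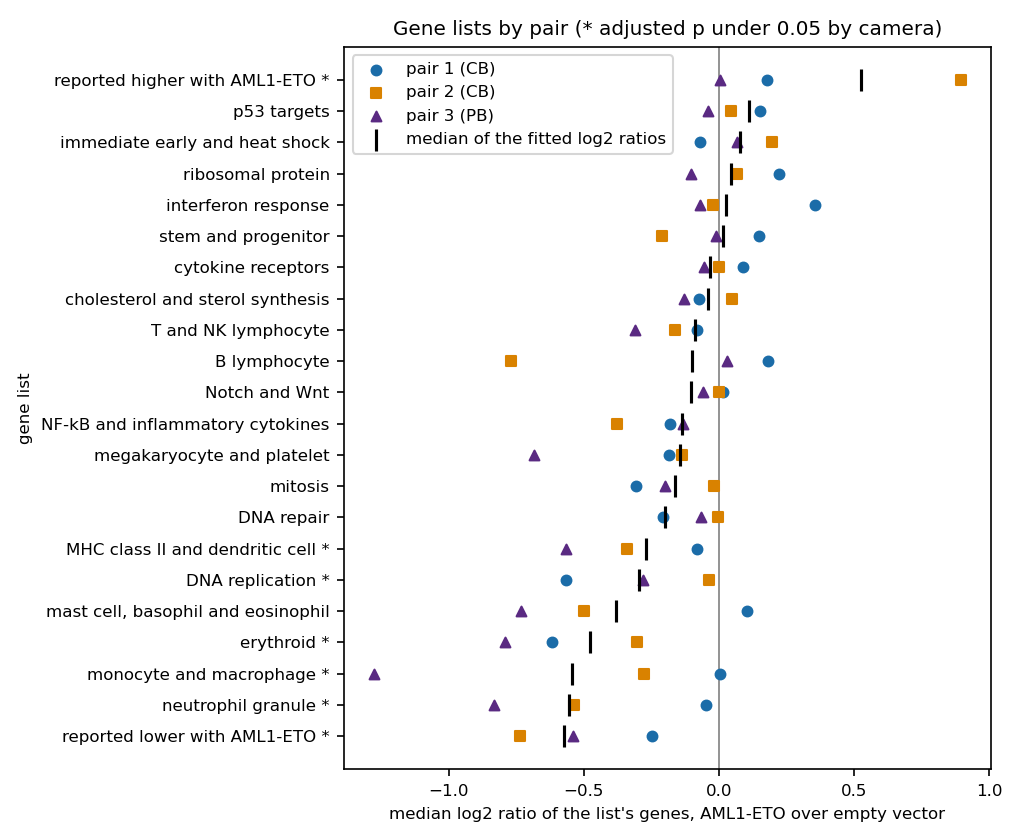
Median log2 ratio of AML1-ETO over empty vector (x axis) of the tested genes of 22 lists (y axis), by pair (symbols) and over the fitted ratios of all 6 arrays (bars); stars mark the 7 lists past camera's threshold. The monocyte and macrophage medians spread from 0.00 in pair 1 to -1.28 in pair 3, and the erythroid medians lie between -0.30 and -0.79.

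Whether the difference between AML1-ETO and empty vector was another in the PB pair than in the CB pairs was tested on the log2 ratios. The single PB pair was assumed to vary like the CB pairs. Across probe sets the SD of the log2 ratios was 1.12 in the PB pair, against 0.57 and 0.89 in the CB pairs. The assumption may thus not hold, and the counts of this test may reflect the wider spread of the PB pair. No probe set passed (limma, 0 calls, smallest adjusted p = 0.464), with 1044 at an unadjusted p under 0.05. With 1 PB pair, whose spread is taken from the CB pairs, 0 calls says little about whether the pairs differ, and the code and the replicate cannot be told apart.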

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

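For 3 gene lists the CB pairs had medians of 1 sign and the PB pair the opposite sign; the difference was not tested for the lists, and only 1 PB pair exists. The ribosomal protein medians were 0.22 and 0.07 in the CB pairs and -0.10 in the PB pair, a difference of -0.25. The p53 target medians were 0.15, 0.04 and -0.04, a difference of -0.14. The Notch and Wnt medians were 0.02, 0.00 and -0.06, a difference of -0.07. None of these lists passed camera.

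Among probe sets found in only 1 table, which entered no comparison, 1 of PRKX, a protein kinase, was higher in AML1-ETO in the only pair that measured it (log2 ratio 2.27, with the vector array at the floor). In the same single pair, probe sets of HOXB6, CSF1R and TGFA had log2 ratios of -2.28, -2.09 and -1.70. The probe sets of the other array design had mean log2 ratios over its 2 pairs of 0.18 for PRKX and -0.61 for TGFA. The means there were 0.25 for HOXB6 (pair ratios -0.24 and 0.74) and 0.25 for CSF1R (0.21 and 0.29).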

How the results depend on the processing

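Array weights, the 3'/5' covariate and the estimated correlation with the block were chosen after seeing the data. Over the alternatives, 0 of 344 values of the named genes reversed, and 5 passed the threshold. These genes were picked for a 2-fold difference in the same direction in every pair. Most alternatives could therefore not turn a sign, and the count of 0 is no evidence of robustness. The count of probe sets past the threshold was 0 under the replicate block and under every alternative run except 2: an intensity trend gave 3 higher and 2 lower, and array weights gave 4 higher. The PB against CB count was 0 in each alternative run for it. The replicate block added the mast cell, basophil and eosinophil list, which did not pass with the block and an estimated correlation (adjusted p = 0.53 with an estimated correlation), and changed no other call. Of the 24 named genes, 2 (CYP1A1 and AP1S2) moved by over 1.5-fold when a replicate was left out. With floors of 20 and 100, 7 did: CYP1A1 was 5.61 and 4.12, NPTX1 3.61 and 2.10, TM4SF1 2.75 and 0.80, RUNX1T1 2.63 and 0.75, BLNK -3.13 and -1.17, CD1B -2.38 and -1.09 and GPER1 -1.95 and -1.09. RUNX1T1 and TM4SF1 were not tested with the filter at 200, and the 344 values do not include RUNX1T1. The larger counts at 1.5-fold and with 1 pair left out follow from the looser criterion; for the other differences the cause was not tested.

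Probe sets 2-fold lower in every pair numbered 44 with a floor of 20, 14 with a floor of 100 and 10 with log2(value + 50). At 1.5-fold, 152 were higher and 131 lower. Leaving out a replicate gave 77 to 223 higher and 74 to 384 lower. For gene lists the counts past the threshold were 0 higher and 0 lower with an estimated correlation, with an estimated correlation and the replicate block, and by fry.

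List medians that reversed were all of uncalled lists except the neutrophil granule list with the 3'/5' covariate. Stem and progenitor was -0.049 with a floor of 20, -0.001 with log2(value + 50), -0.006 with no filter, -0.005 with the filter at 200 and -0.104 with the covariate. Notch and Wnt was 0.087 with no filter, 0.081 on the 4 arrays of the larger table and 0.011 with the covariate. On those 4 arrays B lymphocyte was 0.078 and NF-kB 0.031. With the covariate, neutrophil granule was 0.129, megakaryocyte 0.025, T and NK lymphocyte 0.602 and B lymphocyte 0.159. Leaving out a replicate, medians ranged from -0.265 to 0.119 for stem and progenitor, -0.303 to 0.14 for megakaryocyte, -0.145 to 0.182 for T and NK lymphocyte, -0.472 to 0.078 for B lymphocyte, -0.019 to 0.211 for p53 targets, -0.002 to 0.191 for interferon response, -0.293 to 0.031 for NF-kB, -0.07 to 0.081 for Notch and Wnt and -0.035 to 0.141 for ribosomal protein. Signals near the floor limit small ratios.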

Other observations

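Of 15 tests below, those chosen only after the result was seen were the splits for the counts of probe sets, the turned pairs, the stem and progenitor comparison and the agreement of the CYP1A1 probe sets. The covariate fit of the 58 probe sets, which is not among the 15, was also chosen after. In 4 of the 15 the reading given here departs from the bound set beforehand, and each departure was decided after the values were seen: ties at the floor were left out of a share, the covariate fit was weighed for the monocyte and macrophage list, and a margin of 1 standard error was asked of the liver X receptor and BMP list medians. What each bound gave as first set is stated with it.

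Of the 17 tested genes of the mast cell, basophil and eosinophil list, 6 were lower and 2 (IL4R, 0.55, and HPGD, 0.46) higher in AML1-ETO in every pair. The largest differences were in granule genes of eosinophils: CLC had a mean log2 ratio of -1.72 ± 0.81 (SD, n = 3 pairs), RNASE2 -1.51 ± 0.51, EPX -1.05 ± 0.52 and PRG2 -1.03 ± 0.32. The list did not pass camera with the settings used throughout (adjusted p = 0.10) and passed under 5 alternatives, the replicate block among them. It had adjusted p = 0.75 with an estimated correlation (0.53 with the block too), and its median was -0.10 with the GAPDH 3'/5' covariate (adjusted p = 1). IRF9, part of the interferon-activated transcription factor, was 2.86-fold higher (1.52 ± 0.19) while the median of the interferon response list was 0.03. HSPB1, a small heat shock protein, was 3.26-fold higher (1.70 ± 0.76). In the megakaryocyte and platelet list, CD9 was 2.88-fold higher (1.52 ± 0.46) and PF4 had -1.44 ± 0.99. None of these genes passed the test.

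The first pattern is the 58 probe sets 2-fold different in the same direction in every pair. Against stromal or endothelial cells in the AML1-ETO arrays as its source, 0 of the 5 brightest of 18 such genes (BGN, PECAM1, COL6A1, LOX and TAGLN, mean log2 levels from 8.33 to 9.91) were higher in every pair, and the list median was 0.00, with 2 of the 18 also on a gene list and 7 at 100 or more on every vector array. A small share of such cells is not excluded: SPARC, just under these at a level of 8.20, was higher in every pair (1.70), and PROCR and TM4SF1, which endothelial cells also express, were not on the list. RNA quality and input of the vector arrays stay open: of 607 probe sets 2-fold different the same way in pairs 2 and 3, 270 went the same way in pair 1, which is 58.8% of the 459 with a difference there (exact 95% interval 54.2 to 63.4, too narrow since probe sets are not independent) and, as first set with the 148 ties counted, 44.5%, under the bound of 55% at which RNA quality was to count as the cause. A further 526 probe sets were 2-fold different in opposite ways in pairs 2 and 3. Part of the 607 may therefore agree by chance, which makes the share in pair 1 hard to read. With the GAPDH 3'/5' covariate 52 of the 58 had a fitted ratio of 2-fold or more (CYP1A1 4.96, APOE 3.23, S100A8 -2.75; CTSG -1.16), 42 of them by more than 1 standard error, which does not decide, since all 58 were picked for a 2-fold difference in pair 1 as well; an effect of AML1-ETO stays open and untested.

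The second pattern is the lower lists of blood cell types and of DNA replication. In pair 1 the 3'/5' ratios and spike-ins were alike, and the 18S signal differed the other way from pairs 2 and 3 (462.9 in AML1-ETO against 334.4). There the erythroid and DNA replication medians lay at percentile 0 and percentile 0 of random lists. By the bound set beforehand this argues against RNA quality and input as the whole cause for both lists. The percentile does not decide it, since it rests on 1 pair and does not allow for genes that vary together. Uncalled lists also lay near an extreme in pair 1 (interferon response 100, ribosomal protein 99.9, mitosis 0.01). With the GAPDH 3'/5' covariate the medians were -0.26 for the erythroid list and -0.60 for the DNA replication list. RNA quality and input also stay open for the neutrophil granule list (percentile 9.77), whose median was 0.13 with the GAPDH 3'/5' covariate, reversed. They stay open for the MHC class II and dendritic cell list (percentile 9.57) as well. Its median was -0.29 with the covariate (camera, adjusted p = 0.096), so it did not shrink and the lost call is no evidence for RNA quality. The actin 3'/5' ratio, 1.23 against 1.28 in pair 3, gives little sign of an integrity difference there. For the monocyte and macrophage list the pair 1 median lay at percentile 50.9, which by the bound set beforehand counts for RNA quality as the cause. The list kept its call with the covariate (median -0.52, adjusted p = 0.0011 at camera's preset correlation). It had adjusted p = 0.65 with an estimated correlation and no covariate, the 2 together not being run. The covariate decides for none of these lists, since the GAPDH 3'/5' ratio also differed between replicates (1.07 and 1.08 in pair 1, 1.43 and 1.94 in pair 3). In that fit RNA quality cannot be told apart from the replicate or its code, so the cause stays open. Fewer mature cells of every type cannot be told apart from other causes: the stem and progenitor median was 0.017, short of the 0.25 set for it, and no list of mature cells had a median above 0.

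The third pattern is CYP1A1. A single faulty or cross-hybridising probe set is argued against, since the smallest log2 ratio of its 3 probe sets in any pair was 3.12. A candidate explanation was aryl hydrocarbon receptor activity, but CYP1B1, the target named in advance, had a mean log2 ratio of -0.39 ± 0.71. It was under 2-fold higher in each pair, with ratios of 0.195, -0.195 and -1.184. On the other side, NQO1 (0.96 ± 0.44) and TIPARP (0.59 ± 0.20), which are also targets, were higher in every pair. They had the largest means of the 7 targets tested besides CYP1A1, whose median was 0.10. The rest had 0.15 (ALDH3A1), 0.10 (NFE2L2), -0.16 (SLC7A5) and -0.24 (CYP1A2). By the bound set beforehand, CYP1B1 argues against the receptor, but since its targets went both ways the receptor is not excluded. An effect of AML1-ETO or of the culture on CYP1A1, alone or with other genes, stays open and untested as well.

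Other splits of the arrays were counted for each of these results, and in each case they are too few for a share under 0.05. Of the 4 assignments of direction to the pairs 1, the real one, gave as many 2-fold probe sets (58, highest other 26). Of the 10 splits of the 6 arrays 1, the real one, gave as many lists (7, highest other 6); among the splits that also part all 3 pairs, the others gave 0, 4 and 1 lists. For single probe sets the real split and the highest other gave 0, so 10 of 10 splits gave as many. The splits that keep pair 1 together gave from 1033 to 2484 probe sets at an unadjusted p under 0.05, against 181. Of these, the splits that set pair 1 against pair 3, the pairs that share a table, gave 2484 and 1175. Those that set a single array of pair 3 against the rest of its table gave 1111 and 1033, which does not compare the pairs. The cause of these counts was not tested. The splits that keep pair 2 or pair 3 together and part pair 1 gave 76 and 138.

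Liver X receptor activity was tried as a hypothesis for APOE: the median of mean log2 ratios of 9 other targets was 0.20, with pair medians of 0.07, -0.04 and 0.02. BMP or TGF-beta signalling was tried for ID1: the median of 9 other targets was -0.08, with pair medians of 0.24, -0.79 and 0.36. By the bounds set beforehand, a median under 0.25 in at least 2 pairs, both lists argue against their hypothesis. The members went both ways (PLTP 0.98 and APOC1 -0.30; ID3 1.03 and TGFBI -1.06), and with the margin of 1 standard error neither test decides.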
